A study of Mus musculus with 9 samples.

How the data were processed

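Gene-level RNA sequencing values were taken from 1 table of 14020 genes in 9 libraries of cultured mouse hepatic stellate cells: wild type, Sqstm1 knock-out and a group labelled Nbr1 and Sqstm1 double knock-out, with 3 libraries each and 0 columns left unused. The labels name the culture medium, a time of 4 days and basal conditions. They do not say whether replicates are separate animals or separate cultures, while the series text speaks of biological replicates and describes an Nbr1 knock-out rather than the genotypes of these libraries. P-values therefore measure the spread between these samples. The library kit, its strandedness, the read counter, the gene annotation and any gene filter are not given in the sources used here.

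The deposited signal values are gene read counts that the authors divided by 1 size factor per library. Per the labels, STAR and DESeq2 were among their tools and GRCm39 was the genome build, with no versions given. In each library every value above 0 was a whole multiple of the library's smallest value, within a tolerance of 0.01 (100% of 121126 values). Whole reads were recovered in this way, and the size factors they imply had a correlation of 1 with those DESeq2 computes from the recovered reads. The gene with the fewest reads had 14 over the 9 libraries, and genes absent from the table were not analysed here. Read totals describe counted reads, not sequencing depth. Floors and counting intervals cover counting error only, since reads without molecular identifiers are not independent molecules. A group with no read was given the floor of 3 counts over its libraries.

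The test was limma's moderated linear model with a mean-variance trend on log2 of the value plus 1, over all 9 libraries in 3 groups with no covariate. It took the 10118 genes with a value of at least 10 in at least 3 libraries, with 14 residual degrees of freedom after pooling over the groups and genes. It was two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05, over 3 comparisons. An exact permutation test of 3 libraries against 3 cannot give a p below 0.1. Values are printed as the mean normalized count ± SD of 3 libraries, and log2 fold changes with the SE of the model. Gene lists were tested with limma's camera at a preset correlation between genes of 0.01, again with a correlation estimated for each list, and with fry. A list is said to be called by camera at the preset correlation unless another test is named. The 30 lists were fixed before the data were examined, as were the model, the filter, the comparisons, the rule for naming genes and most alternatives. Of these lists, 22 had at least 5 tested members and entered the tests. They cover interferon-stimulated genes, the STING pathway, antigen presentation, NF-kB targets, inflammatory cytokines, stellate cell activation and matrix, stellate cell quiescence and retinoid handling, smooth muscle, TGF-beta targets, matrix remodelling, NRF2 targets, integrated stress and unfolded protein response, selective autophagy, lysosome and TFEB, lipid storage, cholesterol synthesis, glycolysis and hypoxia, p53 targets, proliferation, ribosomal proteins, tissue dissociation and endothelial markers. Another 6 had fewer members and are given as counts: hepatocyte, cholangiocyte, macrophage, lymphocyte, neutrophil and portal fibroblast markers. Sex-linked and mitochondrial genes were left out of the list tests and are given by gene or count. Versions were R 4.3.3, limma 3.58.1, edgeR 4.0.16 and DESeq2 1.42.0.

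The rule for naming genes took, in each comparison, Sqstm1 and Nbr1, the 10 largest rises and 10 largest falls among called genes whose groups did not overlap and whose higher mean was at least 50 (predicted genes left out), up to 4 members of each list (2 per direction, by smallest p), any STING pathway or selective autophagy gene, and Xist and the Y-linked genes. Of the 6 sex-linked genes listed, 4 had values, all of them Y-linked, so Xist had none. The count of results the rule gave follows. The rule gave 404 results, of which 159 were called. The text prints 113 of these, and some others are not reported here. The printed ones were picked after their values were seen, and partly because their call held when a library was left out, so they are steadier than the rule's genes as a whole. Of the 159 calls, 66 were lost when some single library was left out. The text also gives 16 results outside the rule, for Stat2, Col3a1, Col14a1, Irx2, Hoxb6, Hoxa10 and Sox11, and for Oasl2, Thbs2 and Grem1 in the double knock-out against WT, chosen after their values were seen. For TrnE and TrnQ only library values are given, with no test.

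Genes were matched by name to GENCODE release 21 for mouse, which is on the earlier build GRCm38. It was used only to find neighbouring genes and exons of other genes on the opposite strand. In all 12373 genes were matched (88.3%). Of 9121 tested matched genes, 3625 (39.7%) had such an overlap. Shared calls between comparisons were set against independent lists, and the covariance and correlation of fold changes against 100 simulations with unchanged groups. The method was tested on simulated data made at the depth and spread of these libraries: of 100 genes changed by 1 on the log2 scale 22%, 21% and 22% were called in the 3 comparisons, and of 100 changed by 2, 100%, 94% and 97%, with 3, 3 and 9 calls among unchanged genes. The changed genes were drawn from those with a mean of at least 50, so recovery at lower values was not measured. Alternatives were pseudocounts of 0.5 and 5, no filter, a filter at 50, TMM scaling, quantile normalization, a fit on the 6 libraries compared, the replicate number as a block, library weights, edgeR and DESeq2 on the recovered reads, and each library left out in turn. Where a group keeps 2 libraries, its spread is assumed to be that of the other groups. Restriction to genes with no opposite-strand overlap was added after seeing the data.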

Results

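RNA from cultured mouse hepatic stellate cells was sequenced in 9 libraries. Stellate cells are the vitamin A-storing pericytes of the liver sinusoid, which turn into contractile, matrix-producing myofibroblasts when they are activated. The cells were grown for 4 days without further treatment. The libraries fell into 3 groups of 3: wild type (WT), knock-out of Sqstm1, which encodes the autophagy receptor p62, and a group labelled as double knock-out of Sqstm1 and Nbr1, which encodes a related autophagy receptor. The series addresses how p62 and NBR1 act on the STING pathway, the branch of innate immunity that starts from cytosolic DNA and induces interferon, in stellate cells. The values of 14020 genes rested on 819677, 1257417 and 1467793 reads in the WT libraries, 1060809, 1132945 and 1333537 in Sqstm1 KO, and 1142862, 878241 and 873156 in the libraries labelled double knock-out. Of these genes, 10118 were tested. Many of the highest values belonged to genes whose exons overlap an exon of another gene on the other strand. Pcsk7, a protease gene that lies opposite the contractile gene Tagln, had a mean of 10632 over the 9 libraries and Tagln had 271. Such an overlap was present in 71 of the 100 highest matched genes and in 36.3% of the other matched genes. A value printed for a gene with an overlap can therefore hold reads of its partner, which is named with it, and levels are not comparable between genes. Whether reads were counted on the strand opposite to the gene stays open. If they were, every printed value would be affected, also those of genes with no known overlap. Restriction to genes with no overlap could not remove this. Sqstm1 KO replicate 3 stood apart from the others. It had reads in 12673 genes, and its 10 highest genes took 18.5% of its reads, against 13.9% and 11.5% in the other two of its group. Its correlation with those libraries was 0.853 and 0.847 across genes, and at least 0.878 in the other pairs of a group. Genes are not independent replicates.

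Sqstm1 had a mean normalized count of 240 ± 16.1 in WT, 52.8 ± 29.8 in Sqstm1 KO and 45.7 ± 17.7 in the libraries labelled double knock-out (SD, n = 3 each). It fell in both knock-out groups against WT, with log2 fold changes of -2.30 (SE 0.38; limma adjusted p = 0.0023) and -2.45 (SE 0.38; adjusted p = 0.00116). Its exons overlap those of Mrnip on the other strand. Between the knock-out groups its log2 fold change was -0.15 (SE 0.38; adjusted p = 0.866), and the sign turned without Sqstm1 KO replicate 3 (0.27) or double knock-out replicate 1 (0.21). Nbr1 RNA was not called in the libraries labelled double knock-out against either other group. It stood at 101 ± 7.64 in WT, 78.9 ± 8.85 in Sqstm1 KO and 90.7 ± 17.5 in the double knock-out (SD, n = 3). Its log2 fold change in the double knock-out was 0.19 (SE 0.24; adjusted p = 0.722) against Sqstm1 KO and -0.17 (SE 0.24; adjusted p = 0.735) against WT. A deletion that leaves the rest of the transcript in place would not be seen in a count over the whole gene, so the Nbr1 label was not checked by these values, and every direction drawn from that group rests on its label.

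The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty differed between the genotypes. In WT their mean normalized counts were 73.5 ± 4.93, 65.9 ± 5.84, 20.5 ± 4.86 and 16.5 ± 3.79 (SD, n = 3), and in Sqstm1 KO none of them had a read in any of the 3 libraries. Against the floor of 3 counts over the group, a normalized count of 0.957, they were at least 76.8-fold, 68.8-fold, 21.4-fold and 17.2-fold lower in Sqstm1 KO (limma adjusted p = 1.7e-07, 1.51e-05, 8.3e-05 and 0.000586). In the libraries labelled double knock-out the same genes stood at 49.0 ± 5.23, 15.1 ± 12.5, 20.3 ± 7.16 and 12.2 ± 6.28. All 4 were higher there than in Sqstm1 KO (adjusted p = 4.2e-07, 0.000584, 6.68e-05 and 0.00123). Eif2s3y alone of the 4 was called lower in the double knock-out than in WT (adjusted p = 0.0162). That call was lost without WT replicates 1, 2 or 3 (adjusted p = 0.0867, 0.1 and 0.0909) or double knock-out replicates 1 or 2 (0.0821 and 0.0584). Presence of Y-linked reads therefore went with the group in every comparison with Sqstm1 KO, and no group held libraries of both kinds.

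**Figure D1:**
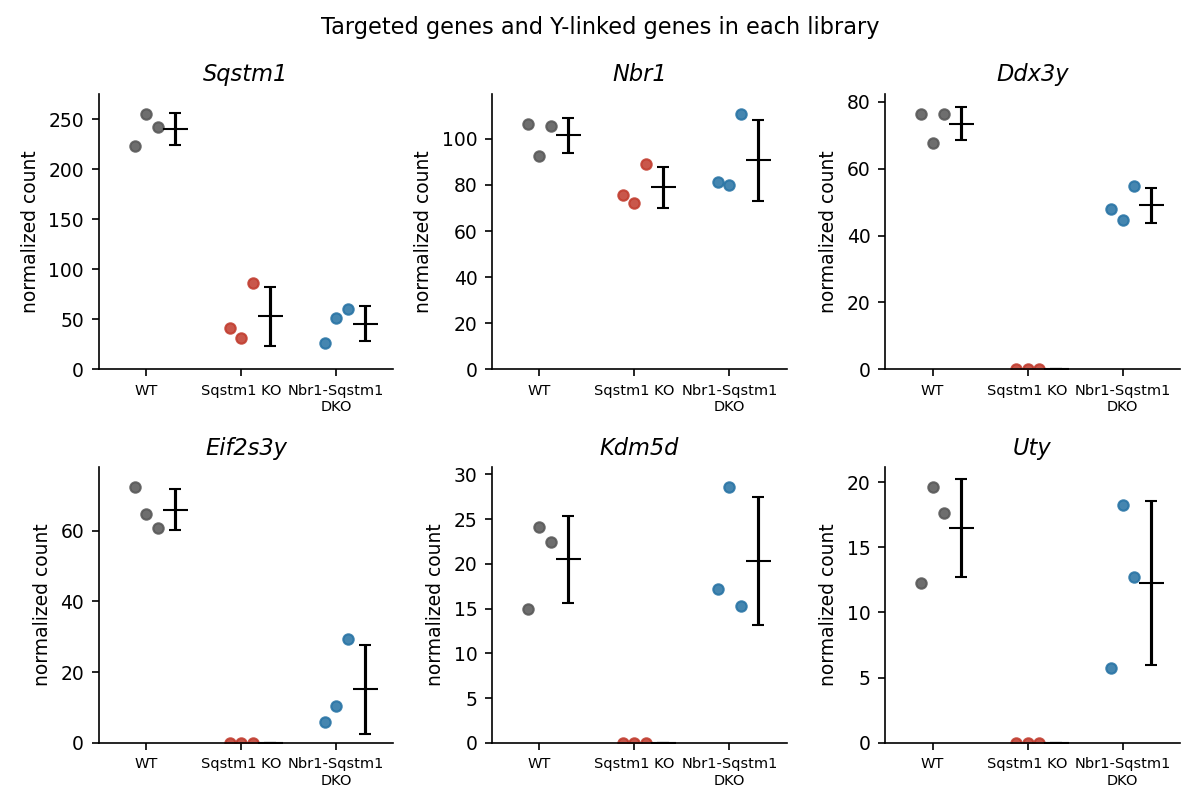
Normalized counts (vertical axes, starting at 0) of Sqstm1, Nbr1 and 4 Y-linked genes in each of the 9 libraries, with the mean and SD of each group of 3 beside the points. Sqstm1 is lower in both knock-out groups, Nbr1 is not lower in the libraries labelled double knock-out than in Sqstm1 KO, and the Y-linked genes are at 0 in all 3 Sqstm1 KO libraries.

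The libraries labelled Sqstm1 KO were first compared with WT. Acta2, which encodes smooth muscle actin alpha and marks activated stellate cells, went from 84.5 ± 8.92 to 819 ± 162 normalized counts (SD, n = 3; log2 fold change 3.25, SE 0.29, limma adjusted p = 1.62e-05), and Col1a2, a chain of type I collagen, from 293 ± 10.9 to 2110 ± 249 (log2 fold change 2.84, SE 0.26, adjusted p = 1.7e-05). Of the 31 tested interferon-stimulated genes 21 fell, among them Oasl2, a member of the oligoadenylate synthetase-like family (57.4 ± 9.25 to 3.67 ± 2.28, log2 fold change -3.75, SE 0.37, adjusted p = 3.8e-05). Trim30a fell with it (55.7 ± 4.00 to 9.22 ± 0.914, log2 fold change -2.47, SE 0.30, adjusted p = 0.000215). In all, 568 genes were called, 246 higher and 322 lower, and 1959 had an unadjusted p under 0.05. Of the 22 lists tested 6 were called, 4 higher and 2 lower, and 3 with an estimated correlation. For 26% of the genes tested the 3 values of each group did not overlap, against 10% by chance.

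Of the 31 tested members of the interferon-stimulated list, 21 fell, 0 rose and 10 were not called. When adjusted over the list alone 24 fell. All 31 fold changes were negative, with a median of -1.78 (camera adjusted p = 1.46e-19; 0.0123 with an estimated correlation). The count of 21 moved to 12, 10 and 9 without WT replicates 1, 2 and 3 and to 13 without Sqstm1 KO replicate 1, while without Sqstm1 KO replicate 3 it was 22 and the median -1.79. Stat2, a subunit of the transcription factor that interferon activates, was among the 21 (51.4 ± 12.3 to 8.52 ± 3.96, adjusted p = 0.00131) and is named after its values were seen. In the antigen presentation list, 2 of 11 members fell, 9 were not called and 5 fell when adjusted over the list alone (median log2 fold change -0.98, camera adjusted p = 0.00878; adjusted p = 0.355 with an estimated correlation). H2-K1, a classical class I heavy chain, was lower (42.2 ± 1.90 to 8.47 ± 2.94, adjusted p = 0.000895). The list's call was lost without WT replicate 1 (adjusted p = 0.0734), Sqstm1 KO replicates 1 or 2 (0.0642 and 0.0898), or double knock-out replicates 2 or 3 (0.0643 and 0.0651). Its count of 2 was 1 without any 1 of the WT replicates, Sqstm1 KO replicate 2 or double knock-out replicates 2 or 3, and 4 without Sqstm1 KO replicate 3, where the median was -1.36. None of the 10 tested STING pathway genes was called (0 by limma, also when adjusted over the list alone, 0 by edgeR and 0 by DESeq2). An unadjusted p under 0.05 was reached by 3 of them, and the list had a median of -0.42 (camera adjusted p = 0.302), or -0.15 without Sqstm1 KO replicate 1. Without Sqstm1 KO replicate 3, 1 member fell. Among them, the DNA sensor Cgas, which overlaps Gm8093 on the other strand, stood at 15.6 ± 3.94 in WT and 9.16 ± 5.19 in Sqstm1 KO (adjusted p = 0.386) and Sting1 itself at 9.88 ± 2.66 and 14.0 ± 3.43 (adjusted p = 0.563). The kinase Tbk1 stood at 61.0 ± 11.0 and 36.3 ± 6.97 (adjusted p = 0.167) and the transcription factor Irf3, whose exons overlap Bcl2l12 on the other strand, at 7.05 ± 4.43 and 15.9 ± 4.89 (adjusted p = 0.151).

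Smooth muscle markers were the list with the largest positive median. Of its 6 tested members 5 rose and 1 was not called. When adjusted over the list alone 5 rose as well (median log2 fold change 2.23, camera adjusted p = 1.41e-07; 0.0123 with an estimated correlation). The count of 5 was 3 without any 1 of the WT replicates or Sqstm1 KO replicate 2. Actg2, the enteric smooth muscle actin, went from 7.05 ± 1.13 to 158 ± 14.3 (adjusted p = 6.06e-07). In the list of stellate cell activation and fibrillar matrix, 9 of 28 members rose, 0 fell and 19 were not called. The list was mixed, with 17 positive and 11 negative fold changes. When adjusted over the list alone 12 rose and 3 fell (median 0.51, camera adjusted p = 3.83e-05; adjusted p = 0.178 with an estimated correlation). Over the 20 members with no exon overlap on the other strand the median was 0.90, and 1 member fell without Sqstm1 KO replicate 2 or double knock-out replicate 2. Besides Acta2 and Col1a2, which have been given, the rise took in Postn, the matricellular protein periostin (10.0 ± 4.10 to 99.0 ± 23.5, adjusted p = 8.3e-05), Col6a3 (16.4 ± 0.125 to 171 ± 81.7, adjusted p = 0.000111) and Timp1, an inhibitor of metalloproteinases (7.26 ± 0.895 to 38.9 ± 15.9, adjusted p = 0.00289). Acta2 and Cnn1 are members of both lists. Of the 18 tested genes of the integrated stress and unfolded protein response, 5 rose, 0 fell and 13 were not called, and 7 rose when adjusted over the list alone (median 0.77, camera adjusted p = 3.38e-05; 0.0188 with an estimated correlation). The count of 5 was 2 without any 1 of the WT replicates or Sqstm1 KO replicate 1, and 3 without Sqstm1 KO replicate 2. Among the members that rose were asparagine synthetase, Asns (23.3 ± 1.54 to 79.2 ± 8.99, adjusted p = 0.00131), and the mitochondrial folate enzyme Mthfd2 (19.0 ± 1.65 to 61.0 ± 6.62, adjusted p = 0.00576). Ribosomal protein genes had a positive median (0.51, camera adjusted p = 0.00209; adjusted p = 0.531 with an estimated correlation), and without Sqstm1 KO replicate 3 the median was 0.16 and the list was not called (adjusted p = 0.232). Of its 25 members 0 were called by limma, also when adjusted over the list alone, 0 by edgeR and 2 by DESeq2, and 7 had an unadjusted p under 0.05.

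The other lists were not called by camera in this comparison. By fry, TGF-beta targets (adjusted p = 0.0281), quiescence and retinoid (0.031) and glycolysis and hypoxia genes (0.0281) were called. So were selective autophagy (fry adjusted p = 0.0245), lysosome and TFEB (0.0281) and lipid storage genes (0.0337). The ribosomal protein list, called by camera, was not called by fry (adjusted p = 0.246). TGF-beta targets had 1 of 13 called, Inhba, a subunit of activin (24.4 ± 2.26 to 79.7 ± 6.97, adjusted p = 0.00173), and 2 rose when adjusted over the list alone (camera adjusted p = 0.117). Among matrix remodelling genes 3 of 14 rose and 1 fell, with 5 and 1 when adjusted over the list alone (adjusted p = 0.37). The gene that fell was Mmp2, which encodes a gelatinase (48.5 ± 13.9 to 8.93 ± 3.13, adjusted p = 0.00138). In the list of stellate cell quiescence and retinoid handling 1 rose and 3 fell of 10, the same numbers when adjusted over the list alone (adjusted p = 0.302). Hand2, a transcription factor of mesenchymal cells, went from 19.0 ± 8.36 to 83.1 ± 47.3 (adjusted p = 0.00578; it overlaps Hand2os1) and Angptl6 from 52.8 ± 7.47 to 3.25 ± 3.25 (adjusted p = 0.000505; it overlaps A230050P20Rik). Glycolysis and hypoxia genes went both ways, with 2 up and 4 down of 21 (4 and 6 when adjusted over the list alone, adjusted p = 0.302), and Pdk1, a kinase that restrains pyruvate dehydrogenase, fell (57.5 ± 4.72 to 20.9 ± 4.48, adjusted p = 0.00571). Of 16 NRF2 targets 1 rose, also when adjusted over the list alone (adjusted p = 0.609). It was the cystine transporter Slc7a11 (4.63 ± 2.55 to 30.9 ± 16.4, adjusted p = 0.0108), whose call was lost without WT replicates 1 or 3 (adjusted p = 0.0654 and 0.0518). Inflammatory cytokines had 1 of 9 higher (2 when adjusted over the list alone, adjusted p = 0.547), the neutrophil chemokine Cxcl5 (0.956 ± 0.831 to 33.5 ± 17.1, adjusted p = 6.61e-05). Selective autophagy genes had 1 of 21 lower, Sqstm1 (1 when adjusted over the list alone, adjusted p = 0.106), and the list was called lower without WT replicate 1 (adjusted p = 0.034). NF-kB targets had 1 of 11 lower (2 when adjusted over the list alone, adjusted p = 0.302). For NRF2 targets, matrix remodelling genes and inflammatory cytokines the median log2 fold change was negative (-0.01, -0.09 and -0.15) and the mean positive (0.14, 0.28 and 0.34), as was the direction of the test. The sign of these medians was not stable. Over members with no exon overlap on the other strand they were 0.08, 0.38 and -0.01. The NRF2 median was 0.18 without WT replicate 3, 0.15 without Sqstm1 KO replicate 1 and 0.02 with quantile normalization. That of matrix remodelling was 0.07 without WT replicate 1 and 0.06 without Sqstm1 KO replicate 3. That of cytokines was 0.10 without WT replicate 3, 0.00018 without Sqstm1 KO replicate 1 and 0.62 with a value of at least 50 required.

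Of single genes outside those lists, Cdh11, a mesenchymal cadherin, went from 0.858 ± 0.914 to 77.0 ± 41.5 (SD, n = 3; limma adjusted p = 1.62e-05). Grem1, an antagonist of bone morphogenetic proteins, fell from 189 ± 33.7 to 17.2 ± 8.45 (adjusted p = 0.000134). Thbs2, the matricellular protein thrombospondin 2, fell from 195 ± 28.6 to 1.17 ± 1.22 (adjusted p = 3.94e-07). Gbp9, of the interferon-inducible guanylate-binding protein family, fell from 88.3 ± 14.5 to 3.32 ± 4.89 (adjusted p = 0.0002), and Nhsl2 from 236 ± 82.5 to 8.21 ± 1.48 (adjusted p = 6.06e-07). Tm6sf1, which overlaps Hdgfl3 on the other strand, fell from 272 ± 67.5 to 0.340 ± 0.589 (adjusted p = 2.48e-08). Among markers of other cells, the macrophage co-receptor Cd14 was lower in Sqstm1 KO (17.6 ± 3.73 to 1.29 ± 1.59, adjusted p = 0.00459), the same direction as the interferon-stimulated genes, and so was Igfbp6, from the portal fibroblast and mesothelial list (25.7 ± 5.59 to 2.30 ± 2.45, adjusted p = 0.00384). Cd14 was the only tested macrophage marker. Cd68, Csf1r and Mpeg1 were below the filter, so a change in macrophages was not assessed. Of the 4 tested members of the list of Igfbp6, 2 rose and 1 fell when adjusted over the list alone. Of the 477 called genes that were matched to the gene annotation, 178 overlapped an exon of a gene on the other strand. Counts of called genes fell to 249, 226 and 282 when WT replicates 1, 2 and 3 were left out in turn.

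The libraries labelled double knock-out were next compared with Sqstm1 KO. By the labels these groups differ in Nbr1, whose loss these values did not check, and they also differed in Y-linked reads. Of the 31 tested interferon-stimulated genes 23 were higher in the double knock-out. Oasl2 went from 3.67 ± 2.28 to 53.3 ± 5.25 normalized counts (SD, n = 3; log2 fold change 3.66, SE 0.37, limma adjusted p = 3.75e-05), Lgals3bp, a secreted glycoprotein, from 3.57 ± 2.53 to 51.1 ± 9.0 (log2 fold change 3.63, SE 0.44, adjusted p = 0.000159) and Stat2 from 8.52 ± 3.96 to 54.4 ± 19.4 (log2 fold change 2.56, SE 0.38, adjusted p = 0.000872). Serum amyloid Saa3, an acute-phase gene, went from 0.951 ± 1.03 to 200 ± 54.8 (adjusted p = 9.59e-06) and complement C3 from 23.8 ± 10.9 to 280 ± 42.1 (adjusted p = 1.58e-05). Hmgcs1, an enzyme early in cholesterol synthesis, stood at 61.9 ± 17.4 and 763 ± 22.9 (log2 fold change 3.64, SE 0.27, adjusted p = 2.43e-06; it overlaps Gm48342). In all, 600 genes were called, 447 higher and 153 lower, and 1905 had an unadjusted p under 0.05. Of the 22 lists tested 12 were called, 7 higher and 5 lower, and 1 with an estimated correlation. The groups did not overlap for 21% of the genes, against 10% by chance.

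Of the 31 tested interferon-stimulated genes 23 rose, 0 fell and 8 were not called, and 28 rose when adjusted over the list alone. All 31 fold changes were positive (median 2.18, camera adjusted p = 2.96e-24; 0.013 with an estimated correlation). With each library left out in turn the count was between 16, without double knock-out replicate 3, and 25, without Sqstm1 KO replicate 3. In the antigen presentation list 5 of 11 rose and 6 were not called, with 5 also when adjusted over the list alone (median 1.64, camera adjusted p = 0.00018; adjusted p = 0.152 with an estimated correlation). The median was 0.82 without WT replicate 1 and 0.70 without Sqstm1 KO replicate 1. It was 0.44 with 3 higher without double knock-out replicate 2, and 0.84 with 2 higher without replicate 3. They included H2-K1 (8.47 ± 2.94 to 59.9 ± 8.78, adjusted p = 0.000131) and H2-D1 (21 ± 5.54 to 68.0 ± 18.2, adjusted p = 0.00438). The STING pathway list was called higher, with 1 of 10 members called, also when adjusted over the list alone (median 0.59, camera adjusted p = 0.0352; adjusted p = 0.152 with an estimated correlation), and without Sqstm1 KO replicate 1 the list was not called (adjusted p = 0.124). The count of 1 was 0 without Sqstm1 KO replicates 1 or 2 or any 1 of the double knock-out replicates. The member was the DNA-binding interferon-inducible gene Ifi204, which belongs to the interferon-stimulated list too (44.3 ± 17.1 to 103 ± 21.8, adjusted p = 0.0243). Its call was lost without Sqstm1 KO replicates 1 or 2 (adjusted p = 0.0837 and 0.0874) or without double knock-out replicates 1, 2 or 3 (0.066, 0.0954 and 0.0708). Cgas stood at 9.16 ± 5.19 and 20.1 ± 9.15 (adjusted p = 0.245), Sting1 at 14.0 ± 3.43 and 26.2 ± 11.4 (adjusted p = 0.305), Tbk1 at 36.3 ± 6.97 and 30.5 ± 4.43 (adjusted p = 0.703) and Irf3 at 15.9 ± 4.89 and 23.1 ± 3.33 (adjusted p = 0.539).

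NF-kB targets rose in 4 of 11 members, 4 also when adjusted over the list alone (median log2 fold change 0.49, camera adjusted p = 0.00131; adjusted p = 0.0757 with an estimated correlation), with Saa3 and C3 among them. Over the 8 members with no exon overlap on the other strand the median was 0.14. The count of 4 was 2 without any 1 of the double knock-out replicates, and the median 0.32 without replicate 2. Stellate cell quiescence and retinoid genes rose in 4 of 10, 4 also when adjusted over the list alone (median 1.25, camera adjusted p = 0.00022; adjusted p = 0.0757 with an estimated correlation). Without double knock-out replicate 1 it was not called (adjusted p = 0.0618; median 0.37, 1 higher). The median was 0.70 without Sqstm1 KO replicate 3 and 0.73, with 2 higher, without double knock-out replicate 2, and 1 was higher without replicate 3. Angptl6, of the angiopoietin-like family, went from 3.25 ± 3.25 to 107 ± 8.68 (adjusted p = 5.55e-05). Inflammatory cytokines rose in 2 of 9, 4 when adjusted over the list alone (median 0.71, camera adjusted p = 0.0128; adjusted p = 0.28 with an estimated correlation). That call was lost without Sqstm1 KO replicate 1 (adjusted p = 0.058). The count of 2 was 1 without Sqstm1 KO replicates 1 or 2 or double knock-out replicates 1 or 3, and 4 without Sqstm1 KO replicate 3. Cxcl5 went from 33.5 ± 17.1 to 180 ± 17.1 (adjusted p = 0.00301). Glycolysis and hypoxia genes rose in 2 of 21, 5 when adjusted over the list alone (median 0.55, camera adjusted p = 0.0183; adjusted p = 0.109 with an estimated correlation). This list was not called without Sqstm1 KO replicates 1 or 2 (adjusted p = 0.0597 and 0.0504). The pair was Pdk1 (20.9 ± 4.48 to 71.9 ± 8.93, adjusted p = 0.00119) and the liver-type phosphofructokinase Pfkl (54.0 ± 14.5 to 137 ± 18.6, adjusted p = 0.0063). TGF-beta targets were not called as a list (2 of 13 higher and 1 lower, 2 and 2 when adjusted over the list alone, adjusted p = 0.312) but were called lower without double knock-out replicate 2 (adjusted p = 0.039). Tgfbi, a matrix protein induced by TGF-beta, rose (4.99 ± 4.14 to 57.9 ± 6.05, adjusted p = 0.00212) and Inhba fell (79.7 ± 6.97 to 30.8 ± 4.05, adjusted p = 0.00675). Beside the rises of this paragraph, the 4 tested portal fibroblast and mesothelial markers had a median of 1.61, with 2 higher, also when adjusted over the list alone. That median was 0.81 without double knock-out replicate 1. The count of 2 was 0 without any 1 of the double knock-out replicates, and 1 without any 1 of the WT replicates or Sqstm1 KO replicates 1 or 3.

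Lists lower in the double knock-out than in Sqstm1 KO had few called members. Of these lists, ribosomal proteins, proliferation and NRF2 targets were not called by fry (adjusted p = 0.191, 0.0942 and 0.0699). The integrated stress and unfolded protein response list fell in 2 of 18, 5 when adjusted over the list alone (median log2 fold change -0.44, camera adjusted p = 0.00536; adjusted p = 0.0757 with an estimated correlation). The median was -0.28 without Sqstm1 KO replicate 3. The count of 2 was 1 without any 1 of the WT replicates or double knock-out replicate 1, and 0 without Sqstm1 KO replicates 1 or 2 or double knock-out replicate 3. Slc7a5, an amino acid transporter, went from 81.5 ± 29.4 to 26.5 ± 9.74 (adjusted p = 0.0145). Its call was lost without Sqstm1 KO replicates 1 or 2 (adjusted p = 0.052 and 0.0675) or double knock-out replicates 1 or 3 (0.0748 and 0.0866). Smooth muscle markers fell in 2 of 6, 2 also when adjusted over the list alone (median -0.55, camera adjusted p = 0.0409; adjusted p = 0.152 with an estimated correlation). The call was lost without Sqstm1 KO replicates 2 or 3 (adjusted p = 0.0994 and 0.0678) or double knock-out replicates 1 or 3 (0.0602 and 0.0784). Its count of 2 was 1 without WT replicates 2 or 3, Sqstm1 KO replicate 1 or double knock-out replicate 2, and 0 without Sqstm1 KO replicate 2 or double knock-out replicates 1 or 3. Acta2 stood at 819 ± 162 and 382 ± 145 (adjusted p = 0.0316). That call was lost without WT replicates 2 or 3 (adjusted p = 0.0666 and 0.0536), Sqstm1 KO replicate 2 (0.0874) or double knock-out replicates 1 or 3 (0.165 and 0.157). The stellate cell activation list was not called (1 of 28 higher and 2 lower, 1 and 7 when adjusted over the list alone, adjusted p = 0.263). Tnc, the matrix protein tenascin C, rose (49.2 ± 16.3 to 159 ± 48.4, adjusted p = 0.00343; it overlaps 8030451A03Rik). Ribosomal protein genes had a median of -0.60 (camera adjusted p = 0.00018; adjusted p = 0.438 with an estimated correlation), and without Sqstm1 KO replicate 3 the median was -0.25 and the list was not called (adjusted p = 0.0806). Proliferation genes had a median of -0.33 (camera adjusted p = 0.0413; adjusted p = 0.427 with an estimated correlation). In these lists 0 of 25 and 0 of 29 members were called by limma, also when adjusted over the list alone, by edgeR and by DESeq2, and 6 and 5 had an unadjusted p under 0.05. Without double knock-out replicate 2, 2 ribosomal protein genes fell, and without Sqstm1 KO replicate 3, 2 proliferation genes fell. The proliferation call was lost without Sqstm1 KO replicate 2 (adjusted p = 0.109) or double knock-out replicates 1 or 3 (0.0689 and 0.147). NRF2 targets had 1 of 16 lower, also when adjusted over the list alone (median -0.35, camera adjusted p = 0.0352; adjusted p = 0.345 with an estimated correlation). This list was not called without Sqstm1 KO replicates 2 or 3 (adjusted p = 0.0604 and 0.126) or double knock-out replicate 1 (0.0907). Its count of 1 was 0 without WT replicates 2 or 3, Sqstm1 KO replicates 1 or 2, or any 1 of the double knock-out replicates.

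Among single genes, Thbs2 went from 1.17 ± 1.22 in Sqstm1 KO to 147 ± 37.8 in the double knock-out (SD, n = 3; limma adjusted p = 7.17e-07) and Tm6sf1 from 0.340 ± 0.589 to 84.7 ± 9.76 (adjusted p = 4.2e-07). The bradykinin receptor Bdkrb2 went from 1.81 ± 3.13 to 87.6 ± 27.5 (adjusted p = 0.0002) and the guidance cue Slit3 from 1.02 ± 1.77 to 58.6 ± 6.54 (adjusted p = 0.000266). Ptprz1, a receptor phosphatase, fell from 64.4 ± 13.7 to 2.73 ± 1.55 (adjusted p = 0.000314), Pter from 269 ± 83.0 to 21.7 ± 10.9 (adjusted p = 1.87e-05) and Lor, which encodes loricrin, from 109 ± 43.8 to 13 ± 7.71 (adjusted p = 0.000485). S100a4, which encodes a calcium-binding protein, fell from 50.5 ± 13.1 to 8.69 ± 2.85 (adjusted p = 0.000737) and the caveolin gene Cav1 from 142 ± 18.9 to 34.2 ± 7.71 (adjusted p = 0.000362). Among matrix remodelling genes 2 of 14 rose and 1 fell, the same numbers when adjusted over the list alone (camera adjusted p = 0.19). Mmp2 rose (8.93 ± 3.13 to 41.8 ± 7.96, adjusted p = 0.00205) and Adamts5, an aggrecanase, fell (200 ± 31.7 to 59.2 ± 3.15, adjusted p = 0.000362). Cd14, the only tested macrophage marker, was higher in the double knock-out (1.29 ± 1.59 to 11.1 ± 5.90, adjusted p = 0.0203), the direction of the interferon-stimulated genes, and that call was lost without double knock-out replicates 1 or 3 (adjusted p = 0.0721 and 0.167). Of 516 matched called genes 208 overlapped an exon on the other strand, and the count of called genes was 293 without double knock-out replicate 1 and 243 without replicate 3.

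**Figure D2:**
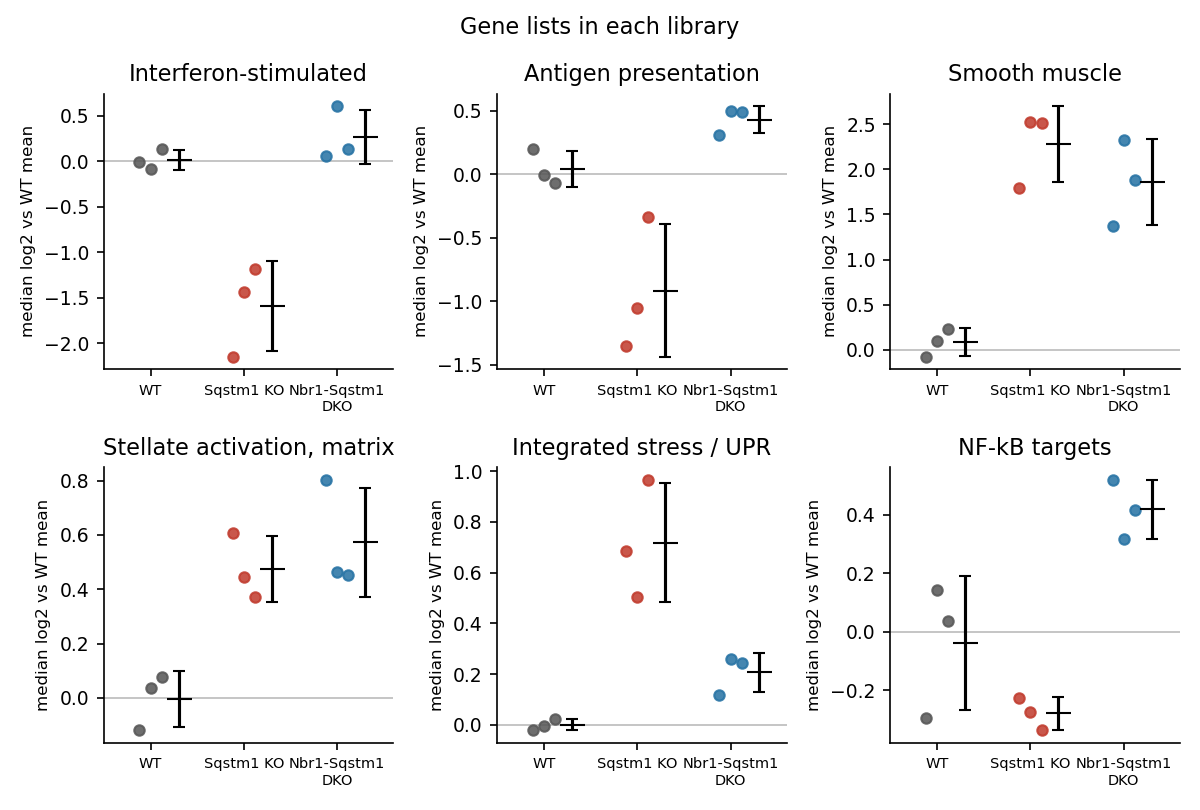
Median over the tested members of 6 gene lists, per library, of the log2 normalized count minus the mean of the WT libraries (vertical axes), with the mean and SD of each group of 3 beside the points. Interferon-stimulated and antigen presentation genes lie below WT in the Sqstm1 KO libraries and above Sqstm1 KO in the libraries labelled double knock-out, while smooth muscle and stellate activation lists lie above WT in both knock-out groups.

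The libraries labelled double knock-out were last compared with WT. Col1a2 stood higher than in WT here too, at 1733 ± 205 against 293 ± 10.9 normalized counts (SD, n = 3; log2 fold change 2.56, SE 0.26, limma adjusted p = 3.36e-05), and so did Acta2, at 382 ± 145 against 84.5 ± 8.92 (log2 fold change 2.10, SE 0.29, adjusted p = 0.000459). The heparin-binding growth factor Ptn went from 1.56 ± 1.36 to 470 ± 66.8 (log2 fold change 7.71, SE 0.43, adjusted p = 2.18e-07), Cxcl5 from 0.956 ± 0.831 to 180 ± 17.1 (adjusted p = 9.08e-07) and Saa3 from 2.02 ± 1.75 to 200 ± 54.8 (log2 fold change 6.28, SE 0.60, adjusted p = 2.05e-05). Hmgcs1 went from 54.9 ± 11.3 to 763 ± 22.9 (log2 fold change 3.79, SE 0.27, adjusted p = 1.63e-06). A total of 650 genes were called, 416 higher and 234 lower, and 2169 had an unadjusted p under 0.05. Of the 22 lists tested 5 were called, all higher, 0 with an estimated correlation, and 3 without WT replicate 1 or double knock-out replicates 1, 2 or 3. The groups did not overlap for 31.2% of the genes, against 10% by chance.

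Of the 31 interferon-stimulated genes 1 rose and 30 were not called, with 0 when adjusted over the list alone. The median was 0.29 (camera adjusted p = 0.14), and -0.087 when a value of at least 50 was required. The count of 1 was 0 without any 1 of the WT replicates or double knock-out replicates 1 or 3, 2 without double knock-out replicate 2 and 3 without Sqstm1 KO replicate 3. It was 2 with edgeR, DESeq2 or the replicate block, 4 with only the 6 libraries compared, 5, with 1 lower, with library weights, and 0 of 12 with a value of at least 50 required. The gene that rose was Dhx58, an RNA helicase of the RIG-I-like family (22.8 ± 4.22 to 76.6 ± 26.5, adjusted p = 0.0355; it overlaps Dhx58os). Its call was lost without WT replicates 1, 2 or 3 (adjusted p = 0.0762, 0.159 and 0.124) or double knock-out replicates 1 or 3 (0.147 and 0.153). Ifit1 stood at 69.8 ± 18.8 and 705 ± 790, with a wide spread in the double knock-out (adjusted p = 0.111). It was called without Sqstm1 KO replicate 3 (adjusted p = 0.0134) or double knock-out replicate 2 (0.0346). Antigen presentation genes had 0 of 11 called by limma, also when adjusted over the list alone, 1 by edgeR and 1 by DESeq2, and 2 had an unadjusted p under 0.05 (camera adjusted p = 0.14). Of 10 STING pathway genes 1 rose, and 3 rose and 1 fell when adjusted over the list alone (median 0.37, camera adjusted p = 0.427). Over the 6 members with no exon overlap on the other strand the median was -0.19. The count of 1 was 0 without WT replicates 1 or 3 or any 1 of the double knock-out replicates, while 3 rose and 1 fell without Sqstm1 KO replicate 3. The member that rose was Irf3 (7.05 ± 4.43 to 23.1 ± 3.33, adjusted p = 0.0312), whose call was lost without WT replicates 1 or 3 (adjusted p = 0.099 and 0.156) or double knock-out replicates 1, 2 or 3 (0.112, 0.0559 and 0.127). Sting1 stood at 9.88 ± 2.66 and 26.2 ± 11.4 (adjusted p = 0.0798) and Tbk1 at 61.0 ± 11.0 and 30.5 ± 4.43 (adjusted p = 0.0607), and both were called without Sqstm1 KO replicate 3 (adjusted p = 0.0393 and 0.0239). Cgas stood at 15.6 ± 3.94 and 20.1 ± 9.15 (adjusted p = 0.799; without double knock-out replicate 2 its log2 fold change was -0.037).

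Smooth muscle markers rose in 3 of 6 members, 5 when adjusted over the list alone (median log2 fold change 1.80, camera adjusted p = 0.000122; adjusted p = 0.0765 with an estimated correlation), with Actg2 going from 7.05 ± 1.13 to 73.7 ± 16.4 (adjusted p = 8.2e-06). The stellate cell activation list rose in 10 of 28, fell in 2 and was not called in 16, with 12 and 4 when adjusted over the list alone (median 0.51, camera adjusted p = 0.00171; adjusted p = 0.272 with an estimated correlation). Its fold changes were positive in 20 members and negative in 8. The 2 that fell were 1 without WT replicate 1, Sqstm1 KO replicates 1 or 2 or double knock-out replicate 1, and 0 without WT replicates 2 or 3 or double knock-out replicate 3. Timp1 went from 7.26 ± 0.895 to 43.2 ± 14.3 (adjusted p = 0.00134). Inflammatory cytokines rose in 1 of 9, Cxcl5, and in 4 when adjusted over the list alone (median 0.60, camera adjusted p = 0.0133; adjusted p = 0.377 with an estimated correlation). The call was lost without WT replicate 1 (adjusted p = 0.0592), and 2 members rose without Sqstm1 KO replicate 2 and 3 without replicate 3. NF-kB targets rose in 3 of 11, 4 when adjusted over the list alone (median 0.33, camera adjusted p = 0.0356; adjusted p = 0.272 with an estimated correlation), with C3 going from 52.5 ± 11.3 to 280 ± 42.1 (adjusted p = 0.000459). The call of that list was lost without WT replicate 1 (adjusted p = 0.0668) or double knock-out replicates 1, 2 or 3 (0.126, 0.368 and 0.141). Its median was 0.67 without WT replicate 3, and 0.59 over the 8 members with no exon overlap on the other strand. Quiescence and retinoid genes rose in 3 of 10, and 4 rose and 2 fell when adjusted over the list alone (median 0.84, camera adjusted p = 0.04; adjusted p = 0.272 with an estimated correlation). The call of the list was lost without WT replicate 2 (adjusted p = 0.0602), Sqstm1 KO replicates 2 or 3 (0.0525 and 0.0557) or double knock-out replicates 1, 2 or 3 (0.879, 0.425 and 0.407). Its count of 3 was 1 without WT replicate 2 and 0 without any 1 of the double knock-out replicates, and the median 0.36 without replicate 1 of these. Without Sqstm1 KO replicate 3 or double knock-out replicate 2, 1 member fell. In the same libraries the 4 tested portal fibroblast and mesothelial markers had a median of 1.51 (0.64 over the 3 with no exon overlap on the other strand), with 2 higher and 3 when adjusted over the list alone. Their median against the WT mean was 1.69, 1.42 and 1.41 in the 3 libraries. Without double knock-out replicates 1, 2 or 3 the median fold change was 0.64, 0.64 and 0.65. The count of 2 was 0 without any 1 of those or WT replicates 2 or 3, and 1 without WT replicate 1.

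Lists not called by camera against WT also had members that changed. By fry, matrix remodelling (adjusted p = 0.0156), selective autophagy (0.0137), glycolysis and hypoxia (0.011) and integrated stress genes (0.00328) were called here. Matrix remodelling genes rose in 6 of 14 and fell in 1, 7 and 3 when adjusted over the list alone (camera adjusted p = 0.127), with the collagenolytic protease gene Ctsk at 17.4 ± 5.31 against 0.404 ± 0.70 (adjusted p = 0.0011) and Adamts5 at 59.2 ± 3.15 against 288 ± 21.8 (adjusted p = 3.36e-05). In cholesterol synthesis Hmgcs1 was the 1 member of 18 called, also when adjusted over the list alone (adjusted p = 0.854). Selective autophagy genes fell in 2 of 21, also when adjusted over the list alone (adjusted p = 0.127): Sqstm1 and the autophagy initiation gene Rb1cc1 (95.8 ± 24.5 to 31.7 ± 3.53, adjusted p = 0.00345; it overlaps 4732440D04Rik). TGF-beta targets rose in 2 of 13 and fell in 1, 3 and 1 when adjusted over the list alone (adjusted p = 0.854), with Tgfbi at 57.9 ± 6.05 against 0.502 ± 0.870 (adjusted p = 5.43e-05). Lipid storage and fatty acid genes fell in 1 of 14, the lipid droplet coat Plin2 (73.8 ± 3.31 to 22.1 ± 8.74, adjusted p = 0.00297), also when adjusted over the list alone (adjusted p = 0.399). Outside the lists, the small proteoglycan decorin, Dcn (1.21 ± 1.59 to 96.2 ± 32.6, adjusted p = 7.58e-06), Cdh11 (0.858 ± 0.914 to 82.2 ± 17.7, adjusted p = 7.58e-06) and Slit3 (0.251 ± 0.435 to 58.6 ± 6.54, adjusted p = 0.000127) rose. Lor (100 ± 31.4 to 13 ± 7.71, adjusted p = 0.000559), Pter (125 ± 34.2 to 21.7 ± 10.9, adjusted p = 0.000418) and the extracellular matrix protein Spon1 (78.9 ± 15.6 to 17.4 ± 3.40, adjusted p = 0.000832) fell. Of 548 matched called genes 240 overlapped an exon on the other strand. The count of called genes was 388, 274 and 309 without WT replicates 1, 2 and 3, 307 and 251 without double knock-out replicates 1 and 3, and 1409 without Sqstm1 KO replicate 3. That last library is in neither group of this comparison and acts on it through the pooled spread and the filter. A gene not called against WT here may therefore still have changed.

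**Figure D3:**
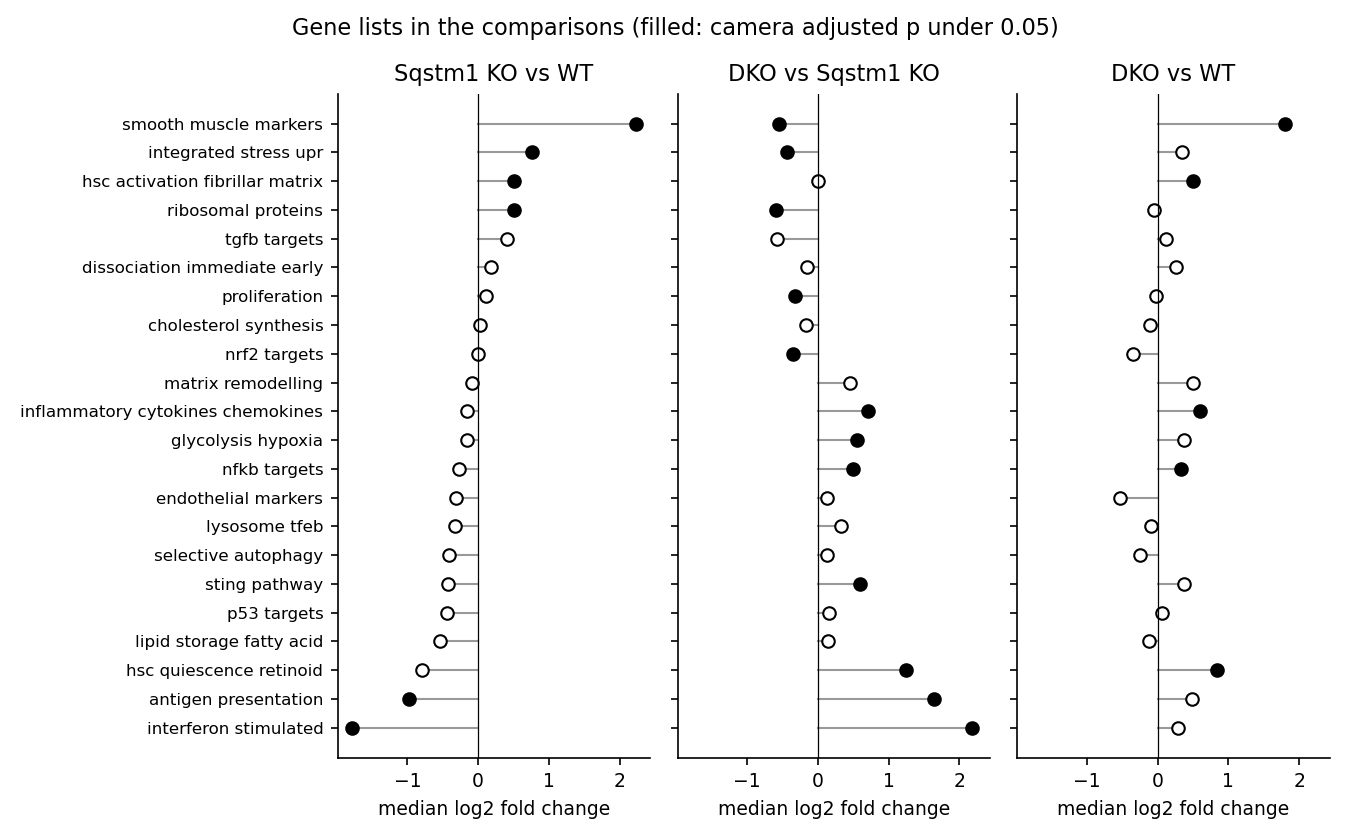
Median log2 fold change (horizontal axes) of each of the 22 gene lists tested, in the 3 comparisons; filled points mark lists with a camera adjusted p under 0.05 at a preset correlation, and hsc stands for hepatic stellate cell. The interferon-stimulated list lies at -1.78, 2.18 and 0.29.

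Selective autophagy, matrix remodelling and TGF-beta lists, given in part above, were not called by camera in any comparison with all 9 libraries. Their calls by fry have been given. In the double knock-out against Sqstm1 KO, fry also called the lysosome and TFEB list (adjusted p = 0.0298). Selective autophagy genes had 1 of 21 lower in the double knock-out than in Sqstm1 KO, also when adjusted over the list alone (camera adjusted p = 0.817). It was Rb1cc1 (70.4 ± 8.67 to 31.7 ± 3.53, SD, n = 3; limma adjusted p = 0.0256), whose call was lost without Sqstm1 KO replicate 2 (adjusted p = 0.0861) or double knock-out replicates 1, 2 or 3 (0.105, 0.0579 and 0.0834), and with only the 6 libraries compared (0.0699). The other 6 lists not called by camera in any comparison follow, with their camera adjusted p for Sqstm1 KO against WT, double knock-out against Sqstm1 KO and double knock-out against WT. For p53 targets these were 0.302, 0.332 and 0.902, and 0 of 11 members were called in each by limma, also when adjusted over the list alone, by edgeR and by DESeq2 (1, 0 and 0 with an unadjusted p under 0.05). For genes induced by tissue dissociation they were 0.37, 0.719 and 0.854, with 0, 1 and 2 of 10 members called and 0, 3 and 3 when adjusted over the list alone. For lysosome and TFEB genes they were 0.0619, 0.0716 and 0.854, with 2 of 22 called in each and 2, 2 and 4 when adjusted over the list alone. That list was called lower in Sqstm1 KO than in WT without WT replicates 1 or 2 (adjusted p = 0.034 and 0.042) or Sqstm1 KO replicate 3 (0.00529), and higher in the double knock-out than in Sqstm1 KO without Sqstm1 KO replicate 3 (0.016) or double knock-out replicate 1 (0.0358). For lipid storage and fatty acid genes they were 0.106, 0.719 and 0.399, with 4, 2 and 1 of 14 called and 6, 2 and 1 when adjusted over the list alone. For cholesterol synthesis they were 0.918, 0.958 and 0.854, with 0, 1 and 1 of 18 called, also when adjusted over the list alone. For endothelial markers they were 0.609, 0.798 and 0.854, with 1, 0 and 1 of 5 called and 2, 0 and 3 when adjusted over the list alone. Apart from the 5 endothelial markers, few markers of other cell types passed the filter, which does not measure how many such cells were present. The hepatocyte, cholangiocyte and macrophage lists had 1 tested member each, the portal fibroblast and mesothelial list had 4, and the lymphocyte and neutrophil lists had 0. Of the 4, too few for the list test, 1 fell in Sqstm1 KO against WT and 2 rose in each of the other comparisons (medians 1.61 and 1.51). The hepatocyte marker was Apoa2, which was not called in any comparison. Bicc1, from the cholangiocyte list, stood at 264 ± 52.7 in the double knock-out (SD, n = 3; it overlaps 4930533K18Rik), higher than 109 ± 15.8 in Sqstm1 KO (limma adjusted p = 0.00675) and 69.8 ± 8.65 in WT (adjusted p = 0.000312). The endothelial marker Eng, which overlaps Fpgs, stood at 24.5 ± 5.87 in WT, 88.9 ± 63.9 in Sqstm1 KO (adjusted p = 0.0445) and 81.2 ± 10.4 in the double knock-out (adjusted p = 0.0273). Its first call was lost without WT replicates 1, 2 or 3 (adjusted p = 0.0916, 0.176 and 0.153), Sqstm1 KO replicates 1 or 3 (0.0866 and 0.0734) or double knock-out replicates 1, 2 or 3 (0.0589, 0.0584 and 0.0758). Its second call was lost without WT replicates 1, 2 or 3 (0.054, 0.12 and 0.121) or double knock-out replicates 1, 2 or 3 (0.105, 0.0515 and 0.115). The list of mitochondrial genes had 0 of 7 tested members called by limma or edgeR and 1 by DESeq2 in each comparison (0, 0 and 1 with an unadjusted p under 0.05). Outside that list, the mitochondrial transfer RNA gene TrnE stood at 66.9, 177 and 102 in the double knock-out libraries. It stood at 562, 476 and 409 in WT and at 589, 450 and 534 in Sqstm1 KO. TrnQ stood at 9.56, 10.3 and 12.7 in the double knock-out, 61.3, 61.8 and 55.8 in WT and 27.6, 30.8 and 82.4 in Sqstm1 KO.

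Genes called in Sqstm1 KO against WT were followed into the double knock-out. Of the 322 genes that fell in Sqstm1 KO, 162 were called higher in the double knock-out than in Sqstm1 KO, and 147 of these were not called against WT. The lack of a call does not show a return to the WT level. Of the 322, 63 were called lower than WT in the double knock-out as well. The median log2 fold change of all 322 against WT was -2.07 in Sqstm1 KO and -0.53 in the double knock-out. Of the 246 that rose, 29 were called lower in the double knock-out than in Sqstm1 KO, while 132 were called higher than WT in the double knock-out as well. Of the 21 interferon-stimulated genes that fell, 18 rose in the double knock-out against Sqstm1 KO, 0 were called against WT, and 9 had a mean below that of WT. In all, 191 genes went in opposite directions in the first and the second comparison, where independent lists would share 14.2 of the fallen and 3.72 of the risen genes. Compared with WT, 195 genes went in the same direction in both knock-out groups, where independent lists would share 10.1 higher and 7.45 lower genes. Part of the excess may come from the shared libraries, since both comparisons of a pair use a common group. The covariance of fold changes was -0.33 for the first pair and 0.37 for the second, against -0.091 and 0.0913 from the shared libraries alone. The correlation across genes was -0.459 and 0.501, against -0.499 and 0.50 from the shared libraries alone. Unrelated changes of equal size in the 3 groups would give such values too. The correlation therefore shows no sharing beyond the common group, and cannot exclude it. The count of 191 was 105, 93 and 114 without WT replicates 1, 2 and 3 and 109 without double knock-out replicate 3. The count of 195 was 96, 73 and 87 without the WT replicates, 126 and 103 without double knock-out replicates 1 and 3, and 302 without Sqstm1 KO replicate 3.

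**Figure D4:**
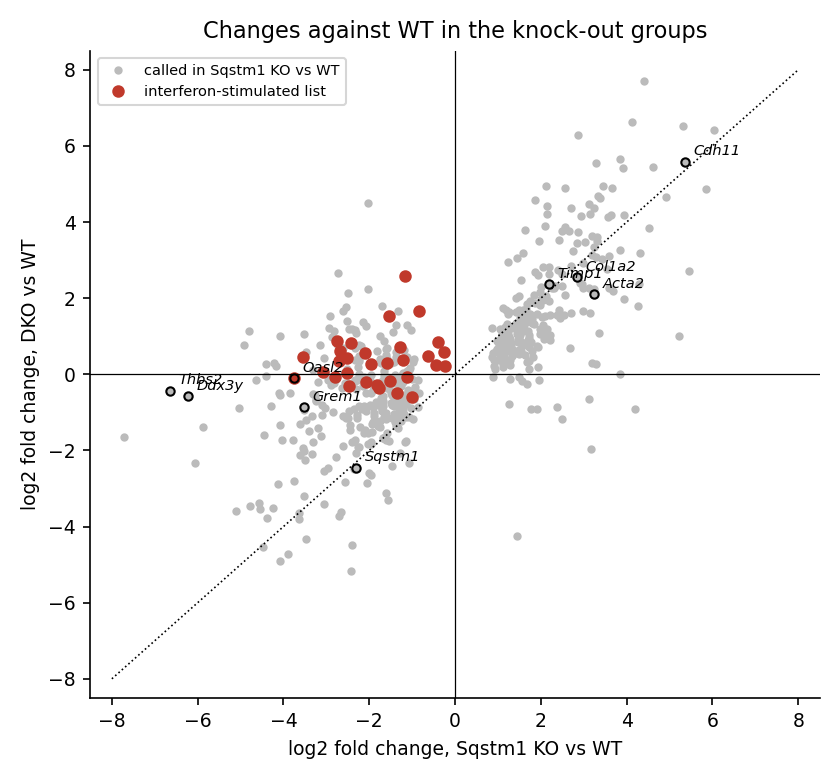
Log2 fold change against WT in Sqstm1 KO (horizontal axis) and in the libraries labelled double knock-out (vertical axis); grey points are the 568 genes called in Sqstm1 KO against WT, red points the 31 tested interferon-stimulated genes, and the dotted line marks equal changes. Both axes share the WT libraries, which by themselves give a positive relation. Acta2, Col1a2, Timp1 and Cdh11 lie above 0 on both axes, while Oasl2, Thbs2 and Grem1 lie below 0 on the horizontal axis and were not called on the vertical axis.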

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

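The restriction to genes with no opposite-strand exon overlap was chosen after seeing the data. In what follows, counts of called genes come in the order Sqstm1 KO against WT, double knock-out against Sqstm1 KO, double knock-out against WT, then the genes opposite in the first pair of comparisons and those with the same direction against WT. With a value of at least 50 required, so with fewer genes tested, they were 290, 291, 360, 96 and 105, with 6 lists called in the second comparison and 2 in the third, and an interferon median of -0.087 against WT in the double knock-out (adjusted p = 0.98). With only the 6 libraries compared, so with fewer samples, they were 352 in the second comparison, 1229 in the third and 109 opposite. The main fit assumes 1 spread for all groups. Against sampling noise, the chi-square per degree of freedom was 19.7 and 25.9 in pairs with Sqstm1 KO replicate 3. It was at most 9.13 in the other pairs of a group. The main fit may therefore call too many genes in comparisons with Sqstm1 KO and too few in the double knock-out against WT. With library weights they were 2639, 1363, 3210, 539 and 1296, with 3 lists in the third comparison, and Nbr1 turned to 0.033 (adjusted p = 0.907) against WT and Sqstm1 to 0.32 (adjusted p = 0.482) between the knock-out groups. DESeq2 gave 296 genes of the same direction. For the last 2 settings the cause was not tested. An estimated correlation left 3, 1 and 0 lists called. Genes with no overlap on the other strand, fewer by construction, gave 299, 308, 308, 100 and 96.

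With each library left out in turn, called genes ranged from 226 to 651, 243 to 764 and 251 to 1409, shared genes from 93 to 219 and 73 to 302, and called lists from 5 to 7, 8 to 13 and 3 to 5. The extremes were 226, 93 and 73 without WT replicate 2, 243 and 251 without double knock-out replicate 3, and 651, 764, 1409, 219 and 302 without Sqstm1 KO replicate 3. Interferon medians ranged from -1.95 to -1.68, 1.83 to 2.28 and 0.13 to 0.42. Sqstm1 ranged from -2.72 to -1.99 and -2.69 to -2.09 against WT, and from -0.46 to 0.27 between the knock-out groups, turning to 0.27 (adjusted p = 0.681) without Sqstm1 KO replicate 3 and 0.21 (adjusted p = 0.85) without double knock-out replicate 1. Nbr1 ranged from 0.04 to 0.28 and -0.33 to -0.09. Cgas ranged from -0.037 (adjusted p = 0.979), without double knock-out replicate 2, to 0.61 against WT. Oasl2, with no call, ranged from -0.17 to 0.03 (0.030 without WT replicate 1, adjusted p = 0.979) in the double knock-out against WT. Apoa2, with no call, ranged from -0.078 (without Sqstm1 KO replicate 2, adjusted p = 0.931) to 0.33 in the double knock-out against Sqstm1 KO, with -0.0023 without double knock-out replicate 1 (adjusted p = 0.998). Of the 159 calls the naming rule took, 93 held with every library left out and 79 in every setting tried. Against WT in the double knock-out, Tbk1 was called in 7 of 19 other settings (adjusted p from 0.000545 to 0.273), Ifit1 in 7 of 20 (6.46e-05 to 0.396), Sting1 in 2 of 19 (0.031 to 0.282), and with library weights alone Grem1 (0.00304 to 0.536) and Apoa2 (0.00686 to 0.705). Library weights alone also called Tbk1 (0.000692 to 0.481) and Apoa2 (0.02 to 0.803) in Sqstm1 KO against WT. At this depth a change of 1 on the log2 scale was called for 22%, 21% and 22% of simulated genes with a mean of at least 50, so most changes of that size would not be detectable. Changes in genes with lower means were not simulated.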

Other observations

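The test of the neighbours of the targeted genes was written before its result was seen; the tests of collagen and homeobox families, of other splits of the libraries and of the patterns weighed below were chosen only after the results were seen. Collagen genes, grouped by the stem of their symbol among 96 such families, rose in 8 of 22 tested members in the double knock-out against WT and fell in 0 (median log2 fold change 0.87, camera adjusted p = 9.94e-06 over the families; adjusted p = 0.978 with an estimated correlation). Col3a1, a fibrillar collagen, went from 217 ± 32.0 to 722 ± 61.1 normalized counts (SD, n = 3; limma adjusted p = 0.000594). Col14a1, a collagen bound to fibril surfaces, went from 0.753 ± 1.30 to 44.3 ± 10.8 (adjusted p = 0.000102). In Sqstm1 KO against WT 6 of the 22 rose (family adjusted p = 0.0656), and Col14a1 stood at 19.8 ± 10.4 (adjusted p = 0.00145).

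Transcription factor genes picked after their values were seen are given here one by one, with no claim on their class. Irx2 fell from 38.1 ± 1.93 in WT to 1.45 ± 2.50 in Sqstm1 KO and 1.27 ± 2.21 in the double knock-out (SD, n = 3; limma adjusted p = 0.00402 and 0.00324), although DESeq2 did not call it (adjusted p = 0.0561 and 0.0534). Hoxb6 fell from 49.0 ± 20.5 to 7.06 ± 3.40 and 3.16 ± 1.77 (adjusted p = 0.00703 and 0.000622), and Sox11 rose from 0.858 ± 0.914 to 17.6 ± 4.63 and 13 ± 2.78 (adjusted p = 0.00132 and 0.00263). Hoxa10 rose from 3.08 ± 1.38 in WT to 34.7 ± 8.01 in Sqstm1 KO (adjusted p = 0.0039) and had 0 reads in the double knock-out (adjusted p = 6.71e-05 against Sqstm1 KO). The homeobox genes whose symbols begin with Hox were not called as a family in Sqstm1 KO against WT (1 of 17 higher and 4 lower, adjusted p = 0.795).

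The highest values often sat at genes with exons of another gene opposite them, with an odds ratio of 4.3 for such an overlap in the 100 highest matched genes (95% interval 2.75 to 6.89), which describes the pattern and tests no explanation. How abundant the transcripts of the opposite genes were was not measured. Counting without regard to strand and sense counting with true antisense transcription both stay open. The prediction for them, written after the data were seen, placed mitochondrial ND6, coded on the other strand of that genome and normally scarce, below COX1. Instead ND6 exceeded COX1 at least 3.86-fold in every library. That ratio cannot decide, because ND5, on the strand of COX1, exceeded it too and levels are not comparable between genes. Counting on the strand opposite to the gene, which requires a stranded kit, stays open: of 4 pairs of a ribosomal protein gene and a gene opposite it, too few to decide, the latter was higher in 3, and it leaves unexplained that ND5, on the same strand as COX1, also had the higher mean (10736 against 1690). The ribosomal protein genes, tried earlier for sense counting, had a median rank of 1050 (143 to 4662) and decide nothing, because their bound was changed after this value was seen. No biological explanation was tested.

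Y-linked transcripts had no read in the Sqstm1 KO libraries. Too few reads is argued against, since 553 reads of the 4 genes would stand in those libraries at the WT level. Cells from female mice and loss of the Y chromosome cannot be told apart: 4 X-linked genes that escape inactivation had a mean log2 fold change of 0.16 (95% interval -0.19 to 0.509), and Kdm6a and Eif2s3x had few reads. Xist, which marks female cells, had no value in any library. Its absence cannot decide either, since the strand of counting and any gene filter are not known. An exchange of labels between Sqstm1 KO and the double knock-out cannot be told apart from correct labels either, since Nbr1, the gene that would tell, differed by 0.187 between them (-0.336 to 0.711). The sex of the animals stays open and may have contributed to every comparison with Sqstm1 KO.

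Interferon-stimulated genes were lower in Sqstm1 KO and not in the double knock-out. Sqstm1 KO replicate 3 as the sole source is argued against, since the list's median was -1.793 without it (camera adjusted p = 3.32e-22). Reads of genes overlapping on the other strand are argued against as well, with a median of -2.009 over the members with no such overlap. That median does not address counting on the strand opposite to the gene. A difference that goes with the missing Y-linked reads, such as sex, cannot be told apart from the genotype, because 0 groups held libraries of both kinds. The genotypes as labelled and differences between the animals or cultures stay open and were not tested.

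DNA of another strain carried along beside a targeted gene would place called genes near it. Of the 200 nearest tested genes around Sqstm1, 5 were called in Sqstm1 KO against WT, and of the other 8920 matched genes 471 (odds ratio 0.46, 95% interval 0.147 to 1.1, Fisher's exact p = 0.105). Around Nbr1, 11 of 200 were called in the double knock-out against Sqstm1 KO, and 505 of 8920 elsewhere (odds ratio 0.97, 0.473 to 1.79, Fisher's exact p = 1). Neither showed more calls near the targeted gene.

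Other splits of the 6 libraries of a comparison into groups of 3 number 10 with the real one, too few for a share under 0.05. In the order of the report's comparisons, the real groups gave 568, 600 and 650 called genes and the highest of the other splits 0 in each; 6, 12 and 5 called lists against 5, 5 and 4; and interferon medians of 1.783, 2.176 and 0.2899 in size against 0.8082, 0.805 and 0.2979. In 1 of the 10 splits, the real one, the result was as large, except that for the interferon median against WT in the double knock-out there were 2. For the shared genes, 1 of 100 splits of the 9 libraries reached the real count, the real one itself: 191 were opposite, against 84 in the highest other split, and 195 had the same direction, against 75. A share of 1 in 100 is the smallest that 100 splits allow, so such counts were rare among random splits. The splits cannot tell the genotype from any other difference that goes with the groups, such as the Y-linked reads. The split test also does not show more sharing than 2 changed comparisons with a common group give.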
